A study of Mus musculus with 8 samples.

How the data were processed

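The series holds 8 Affymetrix Mouse Gene 1.0 ST arrays, 2 in each of 4 groups taken from the sample titles: WT_MIG, KO_MIG, KO_223mut and KO_starmut, each with replicates numbered 2 and 3. Per the labels' protocols, total marrow of knockout and wild-type C57/BL6 mice was transduced by culture on virus producer cells irradiated with 4000 cGy, RNA was extracted with Trizol and labelled with biotin.

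The authors deposited a value table and a gene list. Per the file headers, the array signals were summarised by RMA16, a form of the robust multi-array average, with the probe annotation of release na31 on the mouse build mm9. The authors deposited these values as log2 signals minus the median of each probe set over all 8 arrays. The centring was checked on the values: every probe set has a median of 0 within 7e-07. No level above background is left after that step, so the planned filter on dim probe sets, the choice of the brightest probe set of a gene and a trend of the variance with the level could not be applied, and each probe set was tested on its own. Any step between arrays beyond RMA16 is not given in the sources used here.

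Per the file headers, the authors' list keeps probe sets between the 20th and 100th percentile of raw signal that had an uncorrected p-value under 0.05 in a one-way analysis of variance with unequal variances over the 4 groups. It holds 1264 probe sets, each with that p-value. The authors also deposited the linear fold change (ratio) of the larger over the smaller group and the log2 fold change. The signed fold change, a score, was deposited by the authors as the ratio of the group means, turned into minus its inverse where below 1. The deposited log2 fold changes equal differences of group means computed from the value table within 3.2e-07, and the authors' p-values were recomputed from the value table within 0.00047 on the log10 scale. Over all probe sets the same calculation put 1513 under 0.05 (5.25%, against 1441 by chance) and none after Benjamini-Hochberg adjustment (lowest adjusted p 0.8).

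Gene symbols came only from that list, which was selected on these arrays, so genes are named only among 1081 probe sets with a single symbol (1049 different symbols). The list gives several symbols for 138 probe sets and none for 45, and the 27589 probe sets outside it are unnamed here. A pair of symbols was named only for the probe set of Mir223. Of the symbols, 1012 were found in a RefSeq gene table of assembly GRCm38.p6 and 99 of them have another current symbol. The symbols printed are those of the list. That table was used for names and for which genes neighbour each other, and no coordinates are given because its build differs from that of the array annotation.

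Comparisons were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on the log2 values of all 8 arrays, with the 4 groups as terms and no block. The arrays share 1 estimate of spread with 4 residual degrees of freedom, moderated by eBayes with 3.67 prior degrees of freedom. All 28853 probe sets were tested in each of the 4 comparisons, p-values are two-sided and adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Differences are given as log2 differences with the moderated SE. A simulation with the spread of the real arrays, 28853 probe sets and known changes in KO_MIG against WT_MIG recovered 31 of 50 changes of 0.5, 49 of 50 of 1, and all 50 of 2 (log2), with 8 false calls. In the comparisons without simulated changes it made at most 1 call. The simulated noise was independent between arrays, whereas real arrays of the same replicate number deviated together (below). These rates may therefore not hold for the real arrays.

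Before the data were examined, the groups, the design, the alternatives, 17 gene lists and the rule for named genes were fixed. The rule takes the 12 largest positive and 12 largest negative changes among called genes without overlap between groups. With fewer than 5 in a direction it takes the 5 largest with an unadjusted p under 0.05, as values only. From each list it takes called members (at most 6) or else the 2 with the smallest p, and always Mir223, Igf1r, Mef2c, Hoxa9 and Meis1 where named. The values of 2 genes that the rule takes are not used here, while counts and set tests include them. A list was tested with camera (preset correlation 0.01) and fry among single-symbol probe sets where at least 5 of its genes were named, which held for 1 of the 17 lists, the reported miR-223 targets. The 4 tests of that list were adjusted together. A further 6 lists (lysosome, innate myeloid, ribosome biogenesis, mitochondrial ribosome, ribosomal proteins, DNA replication) were drawn up after the names in the authors' list had been seen, and their 24 tests were adjusted together.

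Whether the replicate numbers pair the arrays was checked on the values, since the labels do not say. Deviations of same-numbered arrays from their group means correlated at 0.36 to 0.53 in all 6 pairs of groups, and 6 of 8 arrays correlated best with an array of their own number. The fit with the number as a block, planned as an alternative, is therefore given beside the results whose calls it changes. This was decided after the calls of both fits had been seen, and the fit without the block stays the main one.

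Alternatives were centring of each array on its median, the mean of all probe sets of a gene, the replicate number as a block, only the arrays of the groups compared, leaving out each array in turn, an estimated correlation and fry for lists, and Spearman's rho for the correlation. Robust eBayes and leaving out KO_starmut replicate 3 in comparisons that do not contain it were added later. The planned tests of seed sites in 3' untranslated regions need transcript sequences and were not run. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.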

Results

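Gene expression was measured on 8 oligonucleotide arrays of mouse bone marrow cells that carried the leukaemia-associated transcription factors Hoxa9 and Meis1. Marrow from mice labelled as knockouts of the microRNA miR-223, or as wild type, was stimulated for 2 days. It was then transduced with retroviruses for Hoxa9 and Meis1 and selected by YFP sorting and by neomycin at 1.4 mg/ml. The labels form 4 groups of 2 arrays each: wild-type cells (WT_MIG), knockout cells (KO_MIG), and knockout cells of the groups KO_223mut and KO_starmut. The study is known to concern both strands of the miR-223 hairpin, and the names of the mutant groups are read here as vectors with a change in the guide strand for KO_223mut and in the passenger strand for KO_starmut. The labels do not spell out MIG or the mutations. Values were log2 signals from which each probe set's median over the 8 arrays had been subtracted, so they carry differences between arrays but no level above background. All 8 arrays covered 28853 probe sets, with array medians between -0.0126 and 0.0109 and 9 blank cells, all of them in KO_starmut replicate 3. Replicates of a group differed by an SD of 0.166 to 0.185 on the log2 scale. The series calls them biological replicates without saying whether they came from separate mice or cultures, so p-values measure the spread between these arrays only. The precision is limited by the number of arrays.

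The probe set that covers miR-223 is listed under a pair of symbols, Mir223 and F630028O10Rik. It read -0.98 and -1.07 in the WT_MIG arrays labelled replicates 2 and 3, and between -0.08 and 0.15 in the 6 arrays labelled knockout. It was thus higher in KO_MIG than in WT_MIG, by 1.09 ± 0.09 (log2, SE, 2 arrays per group, limma adjusted p = 0.0104), the opposite of what loss of a transcript gives. Whether its probes lie inside the deleted segment is not given in the sources used here, so it does not check the labels, and every direction below rests on the genotype as labelled. Between knockout arms it differed by -0.05 ± 0.09 (KO_223mut minus KO_MIG) and -0.03 ± 0.09 (KO_starmut minus KO_MIG), within the spread of replicates. The array gave no other reading of miR-223 from the vectors.

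The comparison of KO_MIG with WT_MIG asks what the loss of miR-223 changes in these cells. The largest difference was in BC018473, an uncharacterised transcript that was 40.0-fold lower in KO_MIG (log2 difference -5.32 ± 0.08, SE, adjusted p = 2.53e-07). Its WT_MIG arrays read 5.31 and 5.34 and the knockout arrays -0.13 to 0.10. Tmem47, a membrane protein of cell junctions, was 8.84-fold higher in KO_MIG (3.14 ± 0.12, adjusted p = 0.000147). Chi3l1, a chitinase-like secreted protein now named Chil1, was 4.28-fold higher (2.10 ± 0.09, adjusted p = 0.000267), and 1700112E06Rik, now Lrmda, was 3.90-fold higher (1.96 ± 0.10, adjusted p = 0.000635). Cd55, which restrains complement on the cell surface, was 2.47-fold higher (1.31 ± 0.10, adjusted p = 0.00794).

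In all, 39 of 28853 probe sets passed an adjusted p of 0.05 in limma, 15 higher and 24 lower in KO_MIG. In each of the 39 the arrays of both groups did not overlap, which chance gives for 33.3% of probe sets with 2 arrays against 2. The 39 were selected by their p-values on these same arrays, so the lack of overlap is not separate evidence. At an unadjusted p under 0.05 there were 1611 probe sets, against 1443 by chance (2924 with the replicate number as a block). Of the 39, 28 had a single symbol and stood for 25 genes, 3 had several symbols and 8 had none. The other named genes that rose were Mtmr9 (log2 differences 1.13 and 1.04 on 2 probe sets), Nav1 (0.82), the nucleoside transporter Slc29a1 (0.76), E130112L23Rik (0.71), D330045A20Rik (0.70), Klhl5 (0.59) and Megf9 (0.55). The named genes that fell included the chemokine receptor Ccr1 (-1.06 ± 0.14), D14Ertd449e (-0.90 to -0.94 on 3 probe sets), Frmd4b (-0.93) and glutamine synthetase, Glul (-0.89; a further probe set gave -0.85 with an adjusted p of 0.0979). Also lower were the disaccharidase Mgam (-0.88), Tmem171 (-0.87), the water channel Aqp8 (-0.87), the lipase cofactor Apoc2 (-0.85), Btf3l4 (-0.73), Txndc12 (-0.72) and Fgd6 (-0.69). Fam49a (-0.64) and B3gnt8 (-0.61) complete the list of named genes and are named after their values were seen. Adjusted p-values of these genes lay between 0.00794 and 0.05. Among unnamed probe sets, 10349648 was higher by 2.48 ± 0.295 and 10439321 was lower, at -1.63 ± 0.15.

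**Figure D1:**
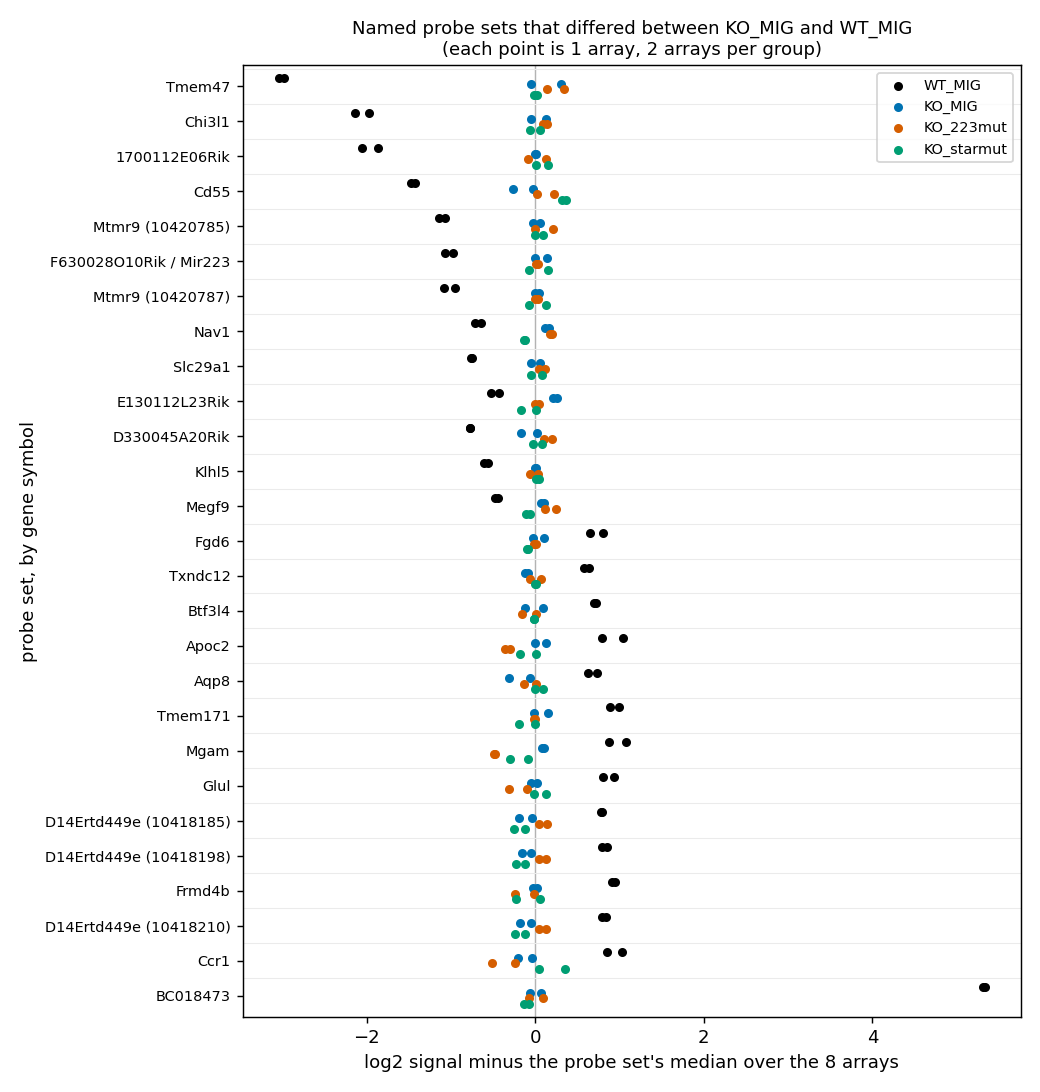
Log2 signal minus the probe set's median over the 8 arrays (x axis) for 27 probe sets that differed between KO_MIG and WT_MIG (y axis), those of the genes taken by the naming rule, without Fam49a and B3gnt8; each point is 1 array and colours mark the 4 groups. In the 27 drawn, both WT_MIG arrays lie beyond all 6 knockout arrays, by at least 0.26 on the log2 scale.

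The call count moved both ways with the fit. With the replicate number as a block it was 277 (105 higher and 172 lower in KO_MIG), which included the 39. Without WT_MIG replicate 2 it was 16, without WT_MIG replicate 3 it was 14, without KO_MIG replicate 2 it was 6, without KO_MIG replicate 3 it was 4, without KO_starmut replicate 3 (a check added after the data were seen) it was 22, and with only the 4 arrays of the 2 groups it was 5. BC018473, Tmem47, Chi3l1 and 1700112E06Rik passed in all 10 alternative settings, with adjusted p-values of at most 0.0213, and the other 20 named items lost their call in at least 1 setting with their direction kept. The block added calls for Itgam (-0.59, adjusted p = 0.0239) and Igll1 (0.33, adjusted p = 0.0455).

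Genes of the lists fixed beforehand could be followed only where the authors' deposited list names them, which held for 20 of 309 genes. The authors chose that list on these arrays, so its directions are not independent evidence. None of the 20 passed over all probe sets in KO_MIG against WT_MIG in the fit without the block, while Itgam and Igll1 passed with it. Of the reported miR-223 targets, 5 of 23 were named: Igf1r, the receptor of insulin-like growth factor 1, at 0.46 ± 0.12 (adjusted p = 0.352), the haematopoietic regulator Lmo2 at 0.41 ± 0.09 (adjusted p = 0.185), Rasa1 at 0.09, Sp3 at 0.06, and the inflammasome component Nlrp3 at -0.46 ± 0.09 (adjusted p = 0.18). Adjusted over the list alone, 3 of the 5 passed, 2 higher (Igf1r and Lmo2) and 1 lower (Nlrp3), in a list that is not independent evidence. As a set the 5 did not stand apart from the 1081 probe sets with a single symbol (camera, adjusted p = 0.428; adjusted p = 0.464 with an estimated correlation).

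Markers of mature myeloid cells in the lists gave -0.59 ± 0.10 for the integrin Itgam (limma adjusted p = 0.126, or 0.0239 with the block). The lysosomal glycoprotein Cd68 gave -0.32 ± 0.07 (adjusted p = 0.199). Progenitor genes gave 0.41 for Lmo2 and -0.22 for Flt3 (adjusted p = 1). The B-lineage gene Igll1 gave 0.33 (limma adjusted p = 0.188, or 0.0455 with the block). The mast cell and basophil gene Cd200r3 differed by 0.32 (adjusted p = 0.504), the eosinophil receptor Ccr3 by 0.11, and the antigen presentation gene Cd74 by -0.15. For the remaining lists, the values were -0.04 for Stat2 (interferon), -0.23 for Tnf (inflammation), -0.39 for Fos (immediate early genes), 0.08 for Dcn and -0.12 for Mmp2 (fibroblasts), and -0.17 for the Y-linked Eif2s3y. From Stat2 to Eif2s3y no adjusted p was under 0.643. With adjustment over the list alone, 1 gene each passed in the lists of Igf1r, Itgam, Cd68, Lmo2, Cd200r3, Igll1, Nlrp3, Fos and Eif2s3y, most of which have 1 named gene, so that the adjusted p is the unadjusted one. No gene of the T and NK cell, erythroid and megakaryocyte, or proliferation lists was named, nor were Hoxa9, Meis1 and Mef2c.

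The comparison of KO_223mut with KO_MIG asks what the vector with the changed guide strand does in knockout cells. No probe set passed in limma (lowest adjusted p = 1), with or without robust variance estimation or the replicate number as a block, and 1171 had an unadjusted p under 0.05 against 1443 by chance (2484 with the block). The following are therefore values, not calls. The named genes with the largest positive differences were Ly6a at 0.58 ± 0.145, Adora3 at 0.40 ± 0.07, Cd96 at 0.39 ± 0.09, Uck2 at 0.38 ± 0.12 and Lage3 at 0.38 ± 0.11. The largest negative ones were Mir142 at -0.70 ± 0.12, Fmnl2 at -0.60 ± 0.08, Mgam at -0.58 ± 0.10, Fam49a at -0.56 ± 0.07 and Itgam at -0.56 ± 0.10. Of the miR-223 targets, Nlrp3 gave -0.35 ± 0.09 and Igf1r -0.18 ± 0.12. Only Nlrp3 passed when adjusted over the list alone, and the set did not stand apart (camera, adjusted p = 0.428). Other list members gave -0.16 for Cd68, -0.24 for Flt3, -0.12 for Lmo2, 0.02 for Cd200r3, -0.07 for Ccr3, -0.19 for Igll1, 0.25 for Cd74, -0.23 for Stat2, -0.07 for Tnf, 0.01 for Fos, 0.26 for Mmp2, 0.10 for Dcn and 0.04 for Eif2s3y. In the lists of Itgam, Cd68, Igll1, Stat2, Mmp2 and Nlrp3, 1 gene each passed when adjusted over the list alone.

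The comparison of KO_starmut with KO_MIG asks the same of the vector with the changed passenger strand. Again no probe set passed in limma, also with robust variance estimation or the replicate number as a block, and 1213 had an unadjusted p under 0.05 against 1443 by chance (2555 with the block). The lowest adjusted p was that of Ly6a, the stem cell antigen Sca-1, at a log2 difference of 1.79 ± 0.145 (3.45-fold, adjusted p = 0.0708). Its KO_starmut arrays read 1.15 and 1.14, its KO_MIG arrays -0.85 and -0.43, and its WT_MIG arrays -0.04 and 0.19. Further positive values were those of Crisp1 (1.27 ± 0.195, adjusted p = 0.679), the myeloid surface peptidase Anpep (1.08 ± 0.23, adjusted p = 0.767), Psg17 (0.97 ± 0.14, adjusted p = 0.587) and the acid phosphatase Acpp (0.82 ± 0.09, adjusted p = 0.272). The largest negative values were those of the RNA sensor Tlr7 (-0.57 ± 0.13), the interleukin 1 receptor Il1r1 (-0.53 ± 0.11), Apobec3 (-0.52 ± 0.07), Fam49a (-0.52 ± 0.07) and Dhrs3 (-0.48 ± 0.06), with adjusted p-values between 0.582 and 0.847.

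Of the miR-223 targets, Lmo2 gave -0.22, Igf1r -0.16 and Nlrp3 0.15 in KO_starmut against KO_MIG. None passed when adjusted over the list alone, and the set did not stand apart (camera, adjusted p = 0.428). Cd200r3 gave 0.60 ± 0.09 (adjusted p = 0.679), Igll1 -0.36 ± 0.07 (adjusted p = 0.767), Flt3 -0.37 ± 0.12 and Cd74 0.38 ± 0.11 (both adjusted p = 1). The other list members were -0.09 for Itgam, 0.04 for Cd68, -0.15 for Ccr3, -0.16 for Stat2, -0.06 for Tnf, 0.25 for Fos, -0.05 for Mmp2, -0.02 for Dcn and 0.16 for Eif2s3y. Adjusted over the list alone, 1 gene passed in each of the mast cell and basophil, B-lineage and progenitor lists, and both Cd74 and Flt3 in the dendritic list.

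The comparison of KO_starmut with KO_223mut sets the vectors against each other on arrays that leave out the shared KO_MIG control. No probe set passed in limma (lowest adjusted p = 0.741), also with robust variance estimation, and 1358 had an unadjusted p under 0.05 against 1443 by chance. With the replicate number as a block 1 passed, the unnamed probe set 10458589 (1.12 ± 0.08, adjusted p = 0.0457), singled out after its value was seen, and 2809 had an unadjusted p under 0.05. Values were largest for Crisp1 (1.42 ± 0.195), Ly6a (1.21 ± 0.145), Anpep (0.71 ± 0.23), the macrophage elastase Mmp12 (0.70 ± 0.12) and Acpp (0.67 ± 0.09) in the positive direction. In the negative direction they were largest for Rassf8 (-0.53 ± 0.07, and -0.29 on a further probe set), Gramd3 (-0.49 ± 0.07), Zc3h12c (-0.42 ± 0.08) and Zbtb8a (-0.40 ± 0.07). Nlrp3 was at 0.50 ± 0.09 (adjusted p = 0.887) and alone among the miR-223 targets passed when adjusted over the list alone. Igf1r was at 0.03 ± 0.12 and Lmo2 at -0.10 ± 0.09, and the set did not stand apart (camera, adjusted p = 0.428). Other members gave 0.47 for Itgam, 0.20 for Cd68, 0.58 for Cd200r3, -0.15 for Hoxa10, -0.16 for Igll1, -0.31 for Mmp2, -0.12 for Dcn, 0.25 for Fos, 0.13 for Cd74, -0.12 for Flt3, 0.07 for Stat2, 0.01 for Tnf, -0.08 for Ccr3 and 0.12 for Eif2s3y. In the lists of Itgam, Cd68, Cd200r3, Mmp2 and Nlrp3, 1 gene each passed when adjusted over the list alone. In the B-lineage list 2 passed, Igll1 among them.

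**Figure D2:**
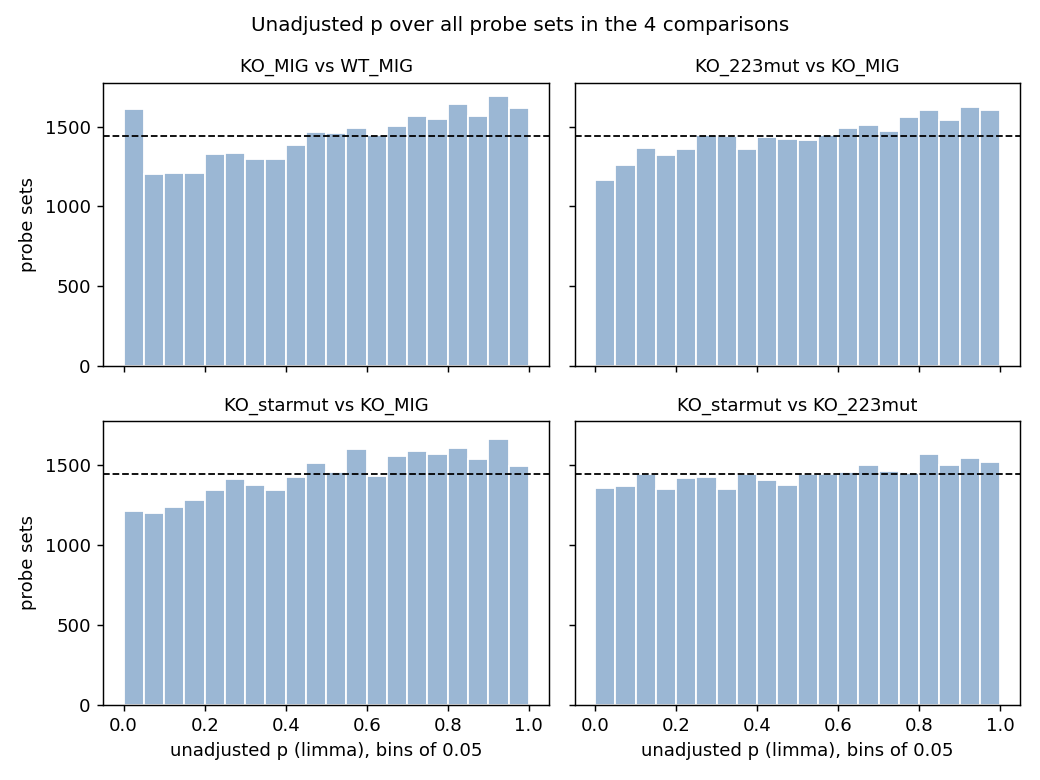
Number of probe sets (y axis) in 20 bins of the unadjusted limma p (x axis) for each of the 4 comparisons; the dashed line marks the 1443 probe sets per bin that chance gives. The lowest bin holds 1611 probe sets in KO_MIG against WT_MIG and 1171, 1213 and 1358 in the comparisons among knockout arms, all 3 of them below the line. These p-values come from the fit without the block. With the replicate number as a block, 2924, 2484, 2555 and 2809 probe sets had an unadjusted p under 0.05. Bins below the line therefore do not show that the knockout arms are alike.

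If the genotype difference came from a lack of the guide strand, and only the KO_starmut vector carried it intact, the difference KO_starmut minus KO_223mut would run opposite to KO_MIG minus WT_MIG. These differences share no array. Across the 28853 probe sets, which are not independent replicates, their Pearson correlation was -0.116 and their Spearman correlation -0.0508. Built from single arrays, the 16 combinations gave correlations from -0.37 to 0.30, with 12 below 0. The widest values came from differences between arrays of unlike replicate number, while the 4 combinations in which both differences joined arrays of the same number, a grouping made after the data were seen, gave -0.093 to -0.0595. Among the 39 probe sets called between KO_MIG and WT_MIG, 24 (61.5%) had opposite signs in the vector comparison. Their median absolute difference was 0.903 between genotypes and 0.115 between vectors, and the slope of the latter difference on the former was -0.0222 ± 0.0217 (SE). This SE treats the 39 probe sets as independent, though some share a gene and all share the same arrays. For BC018473, Tmem47, Chi3l1 and 1700112E06Rik the knockout arrays of all arms stayed between -0.13 and 0.34, far from the wild-type arrays at 5.31 and above for BC018473 and at -1.87 and below for the other genes.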

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

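Robust eBayes and the setting without KO_starmut replicate 3 for KO_MIG against WT_MIG and KO_223mut against KO_MIG were chosen after the data were seen. For KO_MIG against WT_MIG, the 39 calls became 37 with each array centred on its median, 29 with probe sets of a gene averaged and 33 with robust eBayes. They became 5 with only the 4 arrays of the 2 groups, which have fewer degrees of freedom, and 4 to 22 without 1 array, where the lone array of a group is assumed to vary like the others. The comparisons among knockout arms stayed at 0 calls in these settings, and the list of miR-223 targets passed in none. The labels do not say that replicate numbers pair the arrays, although same-numbered arrays deviate together. With the replicate number as a block, KO_MIG against WT_MIG gave 277 calls, including the 39, and KO_starmut against KO_223mut gave 1. Among the genes taken by the naming rule it added Itgam and Igll1 in KO_MIG against WT_MIG and changed no other call, and genes outside the rule were not followed. The correlation for opposite change lay between -0.158 and -0.0395 without 1 array.

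Of 24 named items called in KO_MIG against WT_MIG none changed direction in 10 settings. Among uncalled values, these changed sign when 1 array was left out, over the ranges given. In KO_223mut against KO_MIG, Cd200r3 ranged from -0.061 to 0.102, Tnf from -0.257 to 0.111, Fos from -0.21 to 0.229 and F630028O10Rik|Mir223 from -0.118 to 0.0281. In KO_starmut against KO_MIG, the ranges were -0.145 to 0.0796 for F630028O10Rik|Mir223, -0.207 to 0.0222 for Itgam, -0.11 to 0.0159 for Mmp2 and -0.0357 to 0.00371 for Dcn. In KO_starmut against KO_223mut, they were -0.0471 to 0.309 for Cd74, -0.173 to 0.195 for Tnf, -0.0995 to 0.125 for F630028O10Rik|Mir223, -0.116 to 0.167 for Igf1r, -0.0253 to 0.168 for Stat2 and -0.203 to 0.011 for Lmo2. The cause was not tested. Filters on dim probe sets, the variance trend and the choice of the brightest probe set were not run because the values are centred, and the seed site tests were not run. Signal over background is not kept in the values.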

Other observations

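All gene lists and tests in this part were chosen after the data were seen. The lists hold only genes that the authors' list names, so their directions are not independent evidence, and no result of these lists passed with an estimated correlation. In KO_MIG against WT_MIG, genes of the innate myeloid list, such as innate receptors and complement genes, fell as a set. Of these, 25 of 34 were lower (camera, adjusted p = 0.000126, or 0.236 with an estimated correlation). Adjusted over the list alone, 12 fell and none rose. Among those that fell were the chemokine receptor Ccr1 (-1.06), the receptors Tlr7 (-0.88) and Tlr13 (-1.05), the complement receptor C5ar1 (-0.66) and Csf1 (-0.69). The list does not hold Cd55, which restrains complement and was called higher (1.31), so these counts depend on which genes were put in it. Genes of DNA replication and chromosome segregation were higher in 28 of 29 cases (adjusted p = 0.000126; adjusted p = 0.236 with an estimated correlation), with 11 higher and 1 lower when adjusted over the list alone. Cenpn (0.44), Cdca7 (0.42) and Pold2 (0.29) were among those higher, and E2f2 (-0.48) was the lower one. Both sets kept their call with each of the 4 arrays left out in turn, at adjusted p-values up to 0.00134. Lysosomal genes were lower in 11 of 14 cases (camera, adjusted p = 0.0481, or 0.236 with an estimated correlation), with Pld4 at -0.44 and Hpse at -0.36. Adjusted over the list alone, 4 were lower and 2 higher. The call of the lysosomal set ended with 3 of the 4 left-out arrays. Ribosome biogenesis genes were higher in 22 of 24 cases (adjusted p = 0.0481; adjusted p = 0.649 with an estimated correlation), and 2 of the 4 left-out arrays ended that call (adjusted p up to 0.525), as did fry (adjusted p = 0.0678), centring of each array (0.0525), averaged probe sets (0.0533) and only the 4 arrays of the 2 groups (0.0635). The other 3 sets also passed by fry (adjusted p up to 0.00924).

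Ribosome biogenesis genes were also higher in KO_223mut (24 of 24, median 0.10, adjusted p = 3.06e-05; adjusted p = 0.262 with an estimated correlation) and in KO_starmut (22 of 24, median 0.08, adjusted p = 8.18e-06; adjusted p = 0.24 with an estimated correlation) than in KO_MIG. Mitochondrial ribosomal genes were higher in both arms as well (adjusted p = 0.0229 and 0.000667; adjusted p = 0.236 for each with an estimated correlation). The arms share the KO_MIG arrays and are not independent of each other. For ribosome biogenesis the call held with each of the 4 arrays left out (adjusted p up to 0.0024 and 0.0068), and for mitochondrial ribosomal genes it held in all 4 cases in KO_starmut but in 2 of 4 in KO_223mut (adjusted p up to 0.206). By fry only ribosome biogenesis in KO_223mut passed (adjusted p = 0.0352), while it did not in KO_starmut (adjusted p = 0.0678), nor did mitochondrial ribosomal genes in KO_223mut (adjusted p = 0.0667) and KO_starmut (adjusted p = 0.0501). By camera, lysosomal genes (adjusted p = 0.0314) and innate myeloid genes (adjusted p = 0.0481) were lower in KO_223mut than in KO_MIG. Innate myeloid genes (adjusted p = 0.0481) and ribosomal protein genes (adjusted p = 0.0481) were higher in KO_starmut than in KO_223mut. With an estimated correlation these adjusted p-values were 0.236, 0.236, 0.236 and 0.333, and by fry they were 0.0082, 0.0178, 0.151 and 0.0831. The call for lysosomal genes held in 3 of 4 cases with 1 array left out (adjusted p up to 0.0525). The call for innate myeloid genes between KO_223mut and KO_MIG ended with each of the 4 arrays left out. Between the vectors, 3 of 4 left-out arrays ended the call for innate myeloid genes, and 3 of 4 ended that for ribosomal proteins. Centring of each array ended the calls for innate myeloid genes in both comparisons (adjusted p = 0.0502 and 0.0714), as did averaged probe sets (0.0533 and 0.0535). Averaged probe sets (adjusted p = 0.1) and only the 4 arrays of the 2 groups (0.0525) ended the call for ribosomal proteins. The remaining tests of these lists did not pass by camera. By fry, lysosomal genes also passed in KO_starmut against KO_MIG, with 10 of 14 lower (adjusted p = 0.0082; adjusted p = 0.193 by camera).

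By the positions of their symbols, some genes called between KO_MIG and WT_MIG lie near one another, and the sources of these calls were weighed. Loss of miR-223 that the KO_starmut vector returns in full needs a slope near -1 between the vector and genotype differences over the called probe sets, and the slope was -0.0222 ± 0.0217, which argues against full return of the called genes as a set. Among the 25 called probe sets with a genotype difference under 1 log2 the slope was -0.0922 ± 0.0463, also far from -1. The SEs of both slopes treat probe sets as independent and do not measure the spread between replicate arrays. Partial return of single genes stays open: the ratio of the differences had a median of -0.0657. It was lowest in Ccr1 (-0.542), at 0.58 between the vectors without passing the threshold. Against KO_MIG, Ccr1 was at 0.32 in KO_starmut and at -0.25 in KO_223mut, so part of its vector difference came from KO_223mut. For KO_starmut minus KO_MIG, 18 of the 39 called probe sets ran opposite to the genotype difference, with a median ratio of 0.0132. Loss of miR-223 without return also stays open, since the files do not measure what the vectors express. Segments of another strain carried with the knockout allele would place called genes near one another. Of 25 called genes, 6 had another called gene within 100 genes (Chi3l1 with Nav1, Btf3l4 with Txndc12, 1700112E06Rik with D14Ertd449e). The median was 2 in 10000 random sets of named genes, and a share of 0.1141 of the random sets reached at least 6. Genes were placed by symbol, and where the probe sets themselves lie was not checked, so these pairs may not hold for the probe sets. The random sets leave chance placement among the named genes open as the source of the count. Up to 5 of 25 leading genes had such a neighbour in comparisons among knockout arms. But the named genes were selected on these same arrays, so random sets may hold genes of such segments too. Called probe sets without a single symbol were left out. The count therefore cannot decide between chance and segments. If all came from 1 segment around Mir223, the called genes would lie on its chromosome. Of the 25, 2 did (Tmem47 and D330045A20Rik), against 34 of the 1012 named genes (Fisher's test, p = 0.204). The 25 lay on 13 chromosomes, which argues against 1 segment around Mir223 for the called genes as a set. For single genes such as Tmem47 a segment around Mir223 stays open. With 1012 named genes, segments elsewhere cannot be told apart from chance.

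For the number of probe sets under the authors' uncorrected threshold, chance cannot be excluded over all splits of the arrays. The real grouping put 1513 probe sets under a p of 0.05 in the authors' analysis of variance, and 37 of 100 splits of the 8 arrays into 4 pairs, the real one included, gave as many, with 2700 as the highest other. The other splits that did so all joined arrays of the same replicate number in 2 or 4 of their pairs, and the 8 that joined only such arrays gave 2018 to 2700, which points to a structure of the arrays by number. Of the 22 drawn splits that, like the real one, joined no arrays of the same number, the other 21 gave 779 to 1348. The comparison with all splits therefore turns on the structure by number, and whether the count exceeds chance stays open.

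For limma's F test over the 4 groups after adjustment, 2 of 100 splits gave as many as the real 127, the real one included. Before adjustment, 20 of 100 splits gave as many as the real 2105, with 5328 as the highest other. Because arrays of the same number deviate together, the splits are not interchangeable, so these shares cannot exclude chance. After adjustment, the highest other split gave 128, with the pairs of WT_MIG and KO_223mut kept and the other arrays joined by replicate number. Further splits gave 90 and 78, and these also kept the WT_MIG pair. Splits that did not keep it gave at most 31. The count therefore does not show that the knockout arms differ from one another. Splits that joined no arrays of the same number gave at most 19 besides the real one, and with the replicate number as a block the real grouping gave 374.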
